A study of Zea mays with 9 samples.

How the data were processed

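Endosperm was dissected at 19 DAP (days after pollination) from field-grown, self-pollinated maize of the B73 inbred background, per the labels' protocols. The 9 libraries held poly(A) RNA from WT and from mutants of the thk1-iso15 and thk1-iso17 alleles, with 3 biological replicates per genotype. They were made with a TruSeq kit and sequenced as 100-base paired ends on an Illumina HiSeq instrument, per the labels' protocols. The labels do not say how many plants or kernels went into a replicate. Each p-value measures the spread between these samples, except those for runs of identifiers, which measure the placement of called genes.

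The deposited values are raw counts per gene, with 46430 gene identifiers and 5 summary lines per library. The submitters' processing notes name HISAT2 2.1.0, SAMtools 1.9, StringTie 1.3.6, HTSeq 0.11.1 and the genome build B73 RefGen_v4. The settings of these tools, the gene annotation and the use of strand are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical gene copies, therefore remain uncertain in every count below. The 5 summary lines (no feature, ambiguous, low alignment quality, not aligned, not uniquely aligned) were kept out of library sizes and tests. Genes took between 52.9% and 66.5% of the entries of a library, and entries not uniquely aligned took between 16.8% and 27.0%.

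Gene names came only from a RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which is another build. It was used for names and never for coordinates. It named 518 of the 46430 identifiers: all 208 mitochondrial and 157 plastid genes and 153 of 154 microRNA genes. It named 0 of 44146 nuclear gene models and 0 of 1765 annotated non-coding RNAs. None of 33 gene lists fixed before the data were examined had a member matched by gene symbol. Product descriptions, which alone define some of these lists, were not searched. As 0 nuclear gene models were named, tests of gene lists, product families and chromosome neighbourhoods were not run. The gene targeted by both alleles is not analysed here for the same reason. Of the nuclear genes, only 4 identifiers are given. They are the identifiers with the largest mean fold change, up and down, over both alleles, and the largest rise and fall between the alleles. Each had to pass the test, to have a group mean of at least 5 CPM (counts scaled to a common library total), and to show no overlap between the groups compared. The limit of 2 identifiers in each direction was fixed beforehand. Its division between the comparisons was chosen after the data were examined.

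Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 23529 genes, and libraries were scaled with TMM factors. One quasi-likelihood model (glmQLFit, glmQLFTest) with 3 groups and all 9 libraries gave thk1-iso15 against WT, thk1-iso17 against WT, thk1-iso17 against thk1-iso15, and the mean of both alleles against WT. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 fold changes were taken as the fold change divided by the square root of its F statistic. The common biological coefficient of variation was 0.283. CPM values of single genes are TMM-scaled, and CPM of RNA classes are per total gene counts. A group without a count was assigned 3 counts over the group, which makes a fold against it a lower bound. Intervals and such floors cover counting error only.

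Library measures were compared with two-sided exact permutation tests, adjusted by Benjamini-Hochberg over 24 measures per comparison, some of which overlap in content. With 3 libraries against 3 the smallest possible p is 0.1, and with 6 against 3 it is 0.0119. To compare the number of genes detected, every library was thinned at random to the smallest total, 21871601 counts.

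The pipeline was tested on simulated data with 23529 genes, drawn from the real means and library sizes. For thk1-iso15 against WT it recovered 2.67%, 33.3%, 86.7% and 98% of genes changed 1.5-, 2-, 4- and 8-fold. For thk1-iso17 against WT the shares were 5.33%, 38.7%, 90% and 96.7%. For both alleles together they were 10.7%, 54%, 93.3% and 98.7%. Unchanged genes made up 6.50%, 6.99% and 5.87% of the calls in these 3 comparisons. The changed genes were drawn from those above 1 CPM and changed alike in both alleles, and 2 genes were then called between the alleles, both falsely. Far fewer genes were changed than were called in the data, with 354 calls over all simulated runs against 3642 in thk1-iso15. The adjusted cutoff is stricter when few genes change, so the recovered shares may be too low for the data.

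Alternatives were RLE factors, upper quartile factors, TMM factors computed without the 100 most abundant genes, DESeq2 1.42.0 (Wald test, on the 33773 genes with at least 1 count and with its own filtering), voom in limma 3.58.1, no filter on low counts, a filter of 1 CPM in 3 libraries, fits on the libraries compared alone, the replicate number as a block, each library left out in turn, an adjusted p under 0.01 and a fold change of at least 2. Their effect is given in the closing section.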

Results

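Poly(A) RNA of maize endosperm at 19 DAP was counted per gene in 9 libraries, 3 each from WT, thk1-iso15 and thk1-iso17. The design compares 2 mutant alleles of thk1 with WT in the B73 background. The gene thk1 (thick aleurone1) is named for mutants with extra layers of aleurone, the outer cell layer of the endosperm. The sample titles give the WT libraries as B73. Differences between WT and mutants may therefore include differences of line or of plants that both mutants share. These were not separated from an effect of thk1. Gene counts in WT replicates 1, 2 and 3 came to 24024943, 72288973 and 53538990. In thk1-iso15 they came to 21871601, 40029083 and 47907660, and in thk1-iso17 to 76651742, 49841191 and 48102330. The 23529 genes tested comprised 23304 nuclear gene models, 210 annotated non-coding RNAs and 15 mitochondrial genes. No microRNA gene had a count in any library, and no plastid gene had enough counts to be tested.

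The 3 WT libraries lay apart from the 6 mutant libraries. The first principal component of log2 CPM held 41.2% of the variance, with WT between -90.6 and -72.8 and the mutants between 9.26 and 60.9. Correlations of log2 CPM across genes, which are not independent replicates, ranged from 0.940 to 0.976 within genotypes. Between WT and mutant libraries they ranged from 0.919 to 0.948, and between the 2 alleles from 0.935 to 0.973. In 5670 genes, or 24.1% of those tested, all 6 mutant libraries lay on 1 side of all 3 WT libraries, where chance gives 2.38%. No pair of replicates agreed within sampling noise, as chi-square per degree of freedom was between 40.8 and 162 within genotypes.

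In thk1-iso15 endosperm, 3642 of 23529 genes differed from WT (edgeR quasi-likelihood test, adjusted p under 0.05), of which 2038 were higher and 1604 lower. Higher genes had the larger fold changes. Their median log2 fold change was 1.32, against -0.86 for lower genes, and 577 rose by at least 4-fold while 156 fell by as much. The nuclear gene models held 2036 of the higher and 1591 of the lower calls. Among the annotated non-coding RNAs 2 rose and 13 fell, and 0 of the 15 mitochondrial genes passed. The count was 1466, 1899 and 1839 without WT replicate 1, 2 or 3, and 1962 and 1563 without thk1-iso15 replicate 1 or 2.

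In thk1-iso17 endosperm, 3352 genes differed from WT by the same edgeR test, 1873 of them higher and 1479 lower. By voom the balance turned, with 1692 higher and 1721 lower. The median log2 fold change was 1.37 for higher and -0.82 for lower genes. At least 4-fold changes were reached by 552 higher and 113 lower genes. Nuclear gene models gave 1870 higher and 1471 lower calls, annotated non-coding RNAs 3 and 8, and mitochondrial genes 0. The count was 1417, 1816 and 1583 without WT replicate 1, 2 or 3, and 1196 without thk1-iso17 replicate 1.

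The same genes largely changed in both alleles. Of the genes called, 1318 were higher in both and 968 lower in both, 2286 in all, which is 62.8% of the thk1-iso15 calls and 68.2% of the thk1-iso17 calls. Independent lists of these sizes would share 162 higher and 101 lower genes. A single gene was called in opposite directions. It stood at 15.04 ± 3.73 CPM in WT, 38.7 ± 4.18 in thk1-iso15 and 5.16 ± 2.49 in thk1-iso17 (SD, n = 3 each), with edgeR adjusted p of 0.0136 and 0.00959. Fold changes of the shared genes were of like size, with medians of 1.43 and 1.45 on the log2 scale for higher genes and -0.89 and -0.87 for lower genes in thk1-iso15 and thk1-iso17. The fold was larger in thk1-iso15 for 1158 shared genes and in thk1-iso17 for 1128. The shared count was 891, 1177 and 1073 without WT replicate 1, 2 or 3, 1442 and 1248 without thk1-iso15 replicate 1 or 2, and 966 without thk1-iso17 replicate 1.

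Across all 23529 genes the fold changes of the 2 alleles had a Pearson r of 0.832 and a Spearman rho of 0.815, and 83.2% had the same sign. Both comparisons use the same 3 WT libraries. In 20 simulations with both mutant groups unchanged, the mean r was 0.512, the mean same-sign share 66.8% and the mean number of shared calls 0.05. With no gene changed almost none can be called, so the number of shared calls does not measure what the shared controls add. The covariance was 0.826 against a simulated 0.123, a difference of 0.702. With 3 WT libraries the controls could not be split into parts of at least 2, so part of the excess in shared calls may come from the shared controls.

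**Figure D1:**
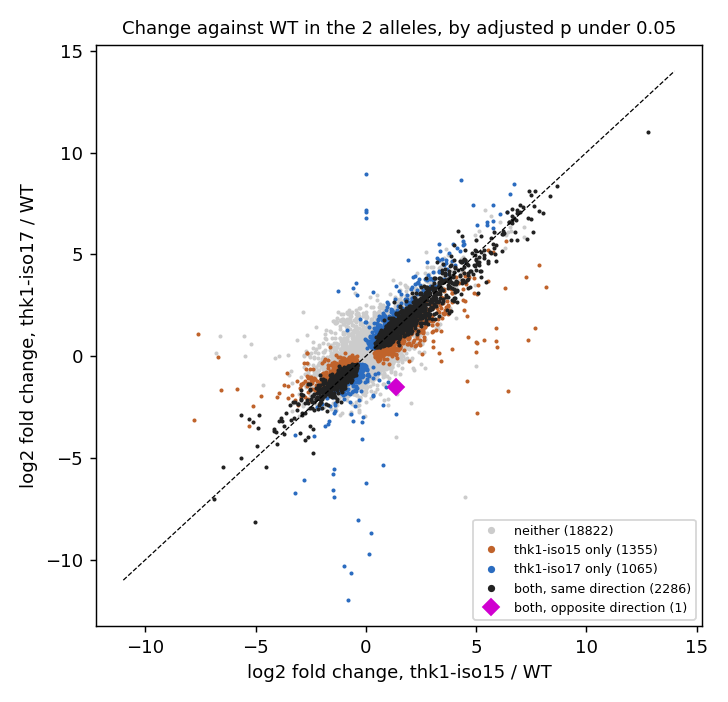
Log2 fold change against WT of each of 23529 genes in thk1-iso15 (horizontal axis) and thk1-iso17 (vertical axis), coloured by the edgeR call in each allele; the dashed line marks equal change. The 2286 genes called in both in 1 direction lie along the line, and 1 gene called in opposite directions lies off it.

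Zm00001d017032 had the largest mean rise over both alleles under the rule for naming. It had 0 counts in all 3 WT libraries and 1438 and 1098 counts over the 3 libraries of thk1-iso15 and thk1-iso17. On the TMM scale it was at least 548-fold higher in thk1-iso15 and at least 233-fold higher in thk1-iso17, against a floor of 3 counts over the WT group. Its level varied widely between replicates, and thk1-iso15 replicate 1 alone held 1205 of the 1438 counts. Without that library the bound in thk1-iso15 was 113-fold. Its edgeR adjusted p was 0.0173 in thk1-iso15 and 0.0356 in thk1-iso17. By voom these were 0.185 and 0.203. Without WT replicate 1, 2 or 3 they were 0.0510, 0.0520 and 0.0550 in thk1-iso15 and 0.0825, 0.0916 and 0.103 in thk1-iso17. In thk1-iso17 the adjusted p was also 0.0780 without its replicate 1 and 0.0570 without its replicate 3.

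Zm00001d027022 had the largest mean fall. It stood at 9.39 ± 0.773 CPM in WT, 0.0889 ± 0.134 in thk1-iso15 and 0.205 ± 0.0948 in thk1-iso17 (SD, n = 3 each). The log2 fold change was -6.47 (SE 0.67, edgeR adjusted p = 0.000633) in thk1-iso15 and -5.47 (SE 0.60, edgeR adjusted p = 0.000964) in thk1-iso17. In thk1-iso15, 11 of its 12 counts came from replicate 3. Without that library 1 count was left and the fitted log2 fold change was -9.06, a value that depends on the prior count. The gene passed in both alleles under every alternative run for it.

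With both alleles combined against WT, 4943 genes differed by the edgeR test, 2586 of them higher and 2357 lower. By voom 2062 were higher and 2358 lower, so the excess of higher genes depends on the test. The count was 2492, 2951 and 2565 without WT replicate 1, 2 or 3. The direction of the edgeR calls differed between ranks of abundance, though no test of this was made. Among the 10 most abundant genes none was higher, and 3 were lower in thk1-iso15 and 4 in thk1-iso17. At ranks 11 to 100, 5 genes were higher and 14 lower in both alleles. At ranks 101 to 1000 the shared calls were 42 higher and 94 lower, and at ranks 1001 to 5000 they were 145 and 301. Below rank 5000 the balance was the other way, with 1126 higher and 557 lower. By voom the excess below rank 5000 was smaller, with 755 higher and 576 lower. By DESeq2 the counts there were 1605 and 840, and with upper quartile factors 1191 and 489. With these factors none of the 10 most abundant genes was called in both alleles. Among the 100 most abundant genes, lower calls outnumbered higher calls in each allele under all 4 scalings (TMM, RLE, upper quartile, and TMM without these genes).

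The most abundant genes accordingly took a smaller share of the mutant libraries. The 10 most abundant genes held 33.6% ± 3.16 of gene counts in WT (SD, n = 3) and 25.5% ± 2.73 in the mutants (SD, n = 6; two-sided exact permutation p = 0.0119, the smallest possible; 0.0952 adjusted over 24 measures). All 6 mutant libraries lay below all 3 WT libraries. The difference thus did not pass the adjustment. The gene ranked first in WT took 8.45% ± 1.51 of WT counts, 5.84% ± 1.31 in thk1-iso15 and 5.79% ± 1.05 in thk1-iso17, and its edgeR adjusted p was 0.0958 and 0.0623. The gene ranked second took 4.53% ± 0.721 in WT, 2.64% ± 0.434 in thk1-iso15 and 2.85% ± 0.610 in thk1-iso17, and fell in both (edgeR adjusted p = 0.0326 and 0.0325). The third fell from 4.10% ± 0.700 to 2.41% ± 0.588 and 2.86% ± 0.215 (edgeR adjusted p = 0.0217 and 0.0356). The fourth took 3.77% ± 0.220, 3.76% ± 1.72 and 2.87% ± 0.548 and passed in neither allele (0.694 and 0.160). The fifth took 3.35% ± 1.10, 2.55% ± 0.421 and 1.92% ± 0.416 and passed in thk1-iso17 alone (0.207 and 0.0388).

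More genes were detected in the mutants at equal depth. With every library thinned to 21871601 counts, 25661 ± 70.6 genes had at least 1 count in WT (SD, n = 3) and 26907 ± 300.0 in the mutants (SD, n = 6). All 6 mutant libraries lay above all 3 WT libraries (two-sided exact permutation p = 0.0119, the smallest possible; 0.0952 adjusted over 24 measures). Again the adjusted value did not pass.

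**Figure D2:**
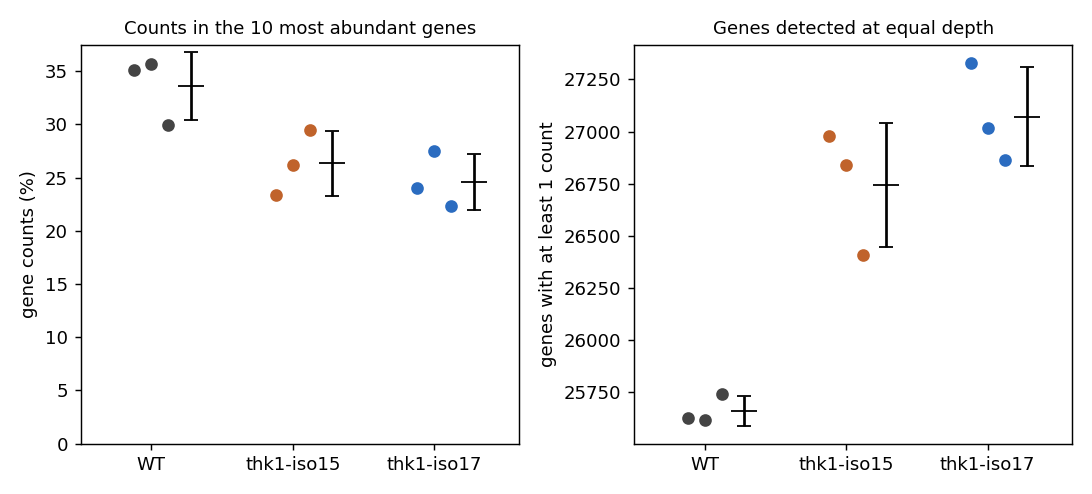
Left, percent of gene counts in the 10 most abundant genes. Right, genes with at least 1 count after thinning to 21871601 counts (axis not starting at 0). Points are libraries and bars are mean ± SD of 3 libraries. The mutants averaged 25.5% against 33.6% in WT on the left and 26907 against 25661 genes on the right.

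Between thk1-iso17 and thk1-iso15, 26 genes differed by the edgeR test, 6 higher and 20 lower in thk1-iso17, with 1618 at an unadjusted p under 0.05. DESeq2 called 197 among all genes with a count and 189 among the 23529 genes of the edgeR fit. All 26 were nuclear gene models. Of 1355 genes called in thk1-iso15 alone, 6 differed between the alleles, and of 1065 called in thk1-iso17 alone, 19 did. The other genes called in 1 allele alone are thus not shown to differ between the alleles. The count was 73 without thk1-iso15 replicate 3.

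Zm00001d016660 had the largest rise in thk1-iso17 over thk1-iso15. It stood at 8.15 ± 5.28 CPM in thk1-iso17, 0.372 ± 0.245 in thk1-iso15 and 0.886 ± 0.392 in WT (SD, n = 3 each). The log2 difference was 4.43 (SE 0.60, edgeR adjusted p = 0.0156). The adjusted p was 0.198 by voom, 0.0619 with these 2 groups alone and 0.0771 without thk1-iso15 replicate 1. Zm00001d013435 had the largest fall. It had 826 counts over the WT libraries (6.31 ± 1.60 CPM) and 778 over the thk1-iso15 libraries (7.05 ± 0.357 CPM), but 1 count over the 3 thk1-iso17 libraries (edgeR adjusted p = 4.81e-06). Per total counts the ratio of thk1-iso15 to thk1-iso17 was 1237, with a 95% exact interval from 221 to 48922. It passed under every alternative run for it.

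None of the 15 mitochondrial genes differed from WT by the edgeR test in either allele, with 0 in thk1-iso15 and 4 in thk1-iso17 at an unadjusted p under 0.05. DESeq2 called 1, ccmFN, higher in thk1-iso17 (adjusted p = 0.0353), and voom called 0. In most of these genes the thk1-iso17 mean rested on replicate 3. An exception was rps2B, at 0.156, 0.136 and 0.172 CPM in replicates 1, 2 and 3, and orf140-b had 0.486 CPM in replicate 2 beside 0.858 in replicate 3. rrn26, the large-subunit ribosomal RNA of the mitochondrion, stood at 151 ± 78.4 CPM in WT, 147 ± 71.1 in thk1-iso15 and 361 ± 377 in thk1-iso17 (SD, n = 3 each), where replicate 3 had 796. The thk1-iso17 log2 fold change of 1.25 (SE 0.64, edgeR adjusted p = 0.209) became -0.0894 without that library. rrn18, the small-subunit ribosomal RNA, had 1.42 (SE 0.82, edgeR adjusted p = 0.265), and -0.49 without it. For cox1, a subunit of cytochrome c oxidase, the values were 2.13 (SE 0.99, edgeR adjusted p = 0.171) and -0.0938. For nad4, a subunit of NADH dehydrogenase, the log2 fold change was 2.49 (SE 0.98, edgeR adjusted p = 0.11), and 0.38 without replicate 3. Of 12 mitochondrial protein-coding genes, 11 had a positive fold change in thk1-iso17 with all libraries and 5 without replicate 3. In thk1-iso15, 5 of the 12 were positive. The difference in the mean of log2 mitochondrial ribosomal RNA per total counts, thk1-iso17 minus WT, was 1.26, and 0.34 without replicate 3, so on that scale the other 2 libraries averaged above WT.

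The annotated non-coding RNAs followed the same library. Their median log2 fold change was -0.73 in thk1-iso15, with 39 of 210 positive. In thk1-iso17 it was 0.43, with 121 positive, and it was -0.43, with 56 positive, when replicate 3 was left out. Without that library the thk1-iso17 count was 3969 genes, the thk1-iso15 count 4385 and the shared count 2626.

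**Figure D3:**
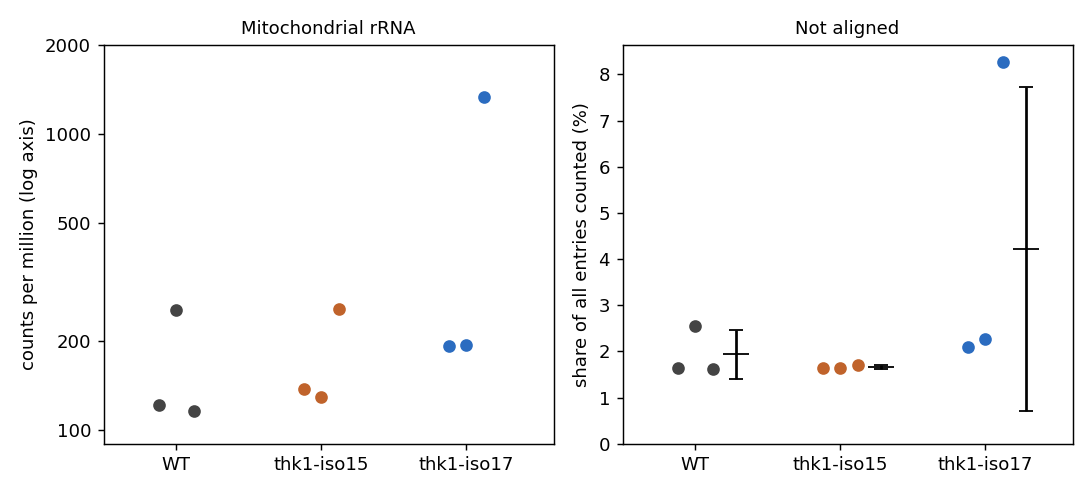
Left, mitochondrial ribosomal RNA in CPM of total gene counts (log axis). Right, percent of entries not aligned, with mean ± SD of 3 libraries. Points are libraries. In thk1-iso17 replicate 3 the values were 1333 CPM and 8.27%, above the other 8 libraries in both.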

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

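The tests of explanations in this part were chosen after the results were seen. The comparison of the alleles itself was fixed before the data were examined.

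In 26 genes the levels differed between thk1-iso17 and thk1-iso15 by the direct edgeR test. The test compares groups of libraries and does not show that the allele is the cause. In Zm00001d016660 the log2 difference was 4.43, and in Zm00001d013435 the fitted value was -9.87, which depends on the prior count since thk1-iso17 had 1 count. Of 10 splits of the 6 mutant libraries, 2 gave at least as many genes as the real split, which is 1 of the 2. A share under 0.05 could not be reached with 10 splits. A random division is thus not argued against here. The real split gave 26 genes and the highest of the other splits gave 38. That split exchanged replicate 3 of the alleles with each other.

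Of the 26 genes, 17 had identifiers within a run of 254 consecutive numbers that held 152 tested genes, and Zm00001d013435 is among them. Of the 17, 15 were lower and 2 higher in thk1-iso17. The most calls in 20 neighbouring tested genes was 7, against at most 3 in 1000 random placements (permutation p = 0.001, the smallest they can give), which argues against random placement. A homozygous deletion of the whole run in thk1-iso17 is excluded. Of 124 genes with at least 1 CPM in WT, 77.4% kept 50% or more of their WT level. Loss of shorter stretches within the run was not tested. Sequence of another parent in that run may lower the alignment of reads to the B73 reference. Such sequence cannot be told apart from a local effect of the allele. Whether the targeted gene lies near the run was not determined here. The labels give no second source of the allele. The thk1-iso17 libraries lay apart from all 6 others in 38.8% of the run's genes and in 3.83% elsewhere (2.38% by chance). The run was drawn around genes that differed in thk1-iso17, so this contrast is partly built in.

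In the same run, 40 genes were lower and 12 higher in thk1-iso17 than in WT, 34.2% of those tested against 14.1% elsewhere. In thk1-iso15, 1 was lower and 4 higher, 3.29% against 15.6%. These shares describe a run drawn around genes called between the alleles, all 17 of them called against WT in thk1-iso17 and not in thk1-iso15, so the contrast is partly built in and no test is given. For the 124 genes of the run with at least 1 CPM in WT, the median level in thk1-iso17 was 76.0% of WT. The quartiles were 52.3% and 106%, and 5 genes lay at or under 10% of WT. In thk1-iso15 the median of the same genes was 102% and 0 lay that low. Among 98 tested genes in the 200 numbers after the run, 4 had a fitted log2 fold change of -5 or less in thk1-iso17 and 0 in thk1-iso15, but 0 of the 4 were called between the alleles. Of 118 tested genes in the 200 numbers before it, 0 lay that low in thk1-iso17. Positions on chromosomes are not used here, so the run is an order of identifiers and not a mapped interval.

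Library thk1-iso17 replicate 3 stood apart in entries outside the comparisons. It had 8.27% not aligned (95% Wilson interval 8.26% to 8.27%), against 1.93% ± 0.525 in WT (SD, n = 3), and 1.29 CPM of plastid genes against 0.129 ± 0.104. Its mitochondrial ribosomal RNA was 1333 CPM (95% Wilson interval 1323 to 1343), 5.19 times the highest other library. An effect of the allele on mitochondrial transcripts stays open. Replicates 1 and 2 of thk1-iso17 both exceeded all WT libraries in 6.67% of the 15 mitochondrial genes, where chance gives 10%, but in 12 of the 15 the highest WT value came from 1 library, so the share rests on that library. Their mitochondrial ribosomal RNA, at 192 and 194 CPM, lay within the WT range of 116 to 255. A candidate explanation is carry-over of RNA without poly(A) tails or of organelles into the library. All 5 classes examined exceeded the highest other library, by 3.14-fold or more, but a single library with no second preparation leaves a change in that sample open.

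Other entries also lay more than 3 SD above the WT mean. In thk1-iso15 replicate 3, 12.3% of entries fell in no feature, 4.87% were ambiguous and 27.0% were not uniquely aligned, against WT means of 9.92%, 3.55% and 20.7%. In thk1-iso17 replicate 1, 11.6% fell in no feature. With 3 WT libraries this limit is itself imprecise.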

How the results depend on the processing

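Alternatives for the run of identifiers, the share of abundant genes, the genes detected and the mitochondrial rRNA totals were chosen after seeing the data. With all libraries kept, 46 of 57 alternative values of the counts and of the correlation stayed within 1.5 times the count or 0.1 of r. At an adjusted p under 0.01 the counts were 904 (thk1-iso15), 844 (thk1-iso17), 1811 (together) and 526 (shared), and with at least 2-fold change 1984, 1839, 2231 and 1233, as stricter limits call fewer genes. The comparison of the alleles gave 197 genes by DESeq2 (189 on the genes tested by edgeR, a run added after seeing the data), 75 with no filter and 17 with those 2 groups alone, and the cause was not tested. With 1 library left out, thk1-iso15 counts ranged from 1466 to 4385, thk1-iso17 from 1196 to 3969, both together from 2492 to 5898, shared from 891 to 2626 and the alleles' difference from 20 to 73. Fewer samples lower the count, but leaving out thk1-iso15 or thk1-iso17 replicate 3 raised it for mutants together. The correlation stayed between 0.786 and 0.858. In thk1-iso17, log2 fold changes with 1 library left out ranged from -0.0894 to 1.78 (rrn26), -0.49 to 2.19 (rrn18) and -0.0938 to 2.64 (cox1), the lowest being those without its replicate 3. Calls in the run of identifiers were 17 of 26 in the main fit, 46 of 197 by DESeq2 and 28 of 75 with no filter. They were 11 of 17 with those 2 groups alone, 10 of 20 without thk1-iso15 replicate 2 and 11 of 23 without thk1-iso17 replicate 2. Of these the share in the run was lowest by DESeq2. By voom the calls were 1404 higher and 1345 lower in thk1-iso15. No scaling moved the median log2 fold change of all genes by over 0.1, but the scalings take most genes as unchanged, so this says little. The balance of calls did move. With upper quartile factors 2045 genes were higher and 1259 lower in thk1-iso17, and 2111 higher and 1527 lower in thk1-iso15. Whether the replicate numbers pair the samples stays open. Of 9 same-number pairs, 3 had correlated deviations above 0.1. In 6 of 9 libraries the best-correlated library of another genotype had the same number. No chance value was computed for these shares. With the replicate block the counts were 3971, 3761, 33, 5373 and 2548 (shared), and r was 0.834; it also called orf140-b higher in thk1-iso17 (adjusted p = 0.0253). DESeq2 gave no adjusted p for 8558 genes against WT and 7904 between alleles, which were left out. Tests of gene lists, product families and neighbourhoods, with their alternatives, were not run. At the present depth and with 3 replicates, 33.3% of simulated 2-fold changes were recovered in thk1-iso15, and neither was varied. The simulation changed far fewer genes than were called in the data, so this share may be too low for them.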

Other observations

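In this part the test of depth was chosen after its result was seen, and so were the splits of the samples. The test without the most abundant genes was set before its result was seen, but its comparison at matched depth was added afterwards.

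Few genes passed a strict rule for absence in 1 state and presence in the other. At or under the floor of 3 counts over the WT libraries (0.0200 CPM of total gene counts) and at 1 CPM or more in all 6 mutant libraries there was 1 gene, called higher in both alleles and at least 129-fold higher on the TMM scale. The reverse was seen in 0 genes. Zm00001d017032, with 0 counts in WT, missed the rule because thk1-iso17 replicate 2, with 37 counts, lay below 1 CPM. The rule thus does not show that such genes are rare. The genes changed in both alleles were not seen to gather in runs of identifiers. The most in 20 neighbours was 6 for higher genes and 5 for lower genes, where random placement gave medians of 6 and 6 (permutation p = 0.97 and 0.99). Random placement of so many calls reached 9 and 8. A run of 7, as found between the alleles, would therefore not stand out, and the test cannot tell whether such a run is present.

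The mutants had 1246 more genes detected than WT at equal depth, so sequencing depth is argued against, the difference at full depth being 1139. Counts freed by the most abundant genes may account for part of it. At 11145588 counts per library the difference was 1218 with all genes kept and 887 without the 100 most abundant genes. Without them the lowest mutant library (26382 genes) stayed above the highest WT library (25844), which argues against counts freed by these 100 genes as the whole cause. Genes of lower rank were kept, and lower shared calls outnumbered higher ones at ranks 101 to 1000 (94 and 42) and 1001 to 5000 (301 and 145). Counts freed by those genes stay open. A wider set of active genes or another mix of cells in the mutant endosperm stays open and was not tested, since the nuclear genes are without names here.

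A random division of the libraries is argued against for mutants against WT. In a model of 2 groups, 1 of 84 splits of the 9 libraries into 3 and 6 gave as many genes. That is the smallest share possible. The real split gave 4962 genes and the highest other 21. For genes shared by both alleles, 1 of 100 drawn splits gave as many, with 2286 against 4. In the model of 2 groups, splits that mixed WT with mutant libraries gave 0 genes, so such splits leave little to share. The shared count thus repeats the separation of WT from the mutants and does not test the overlap of the alleles. For each allele alone, 10 splits are too few for a share under 0.05. The real splits gave 3642 and 3352 genes, each the 1 highest of its 10, and the highest other split gave 0 in both.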
